A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

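The data are 3 columns of a table of array values from Saccharomyces cerevisiae, 1 for each of untreated cells, 30 min and 120 min of rapamycin at 0.2 ng/ul. Per the labels, cells grew in rich medium to an optical density of 0.6, and DNA of chromatin immunodepleted for myc-tagged Maf1 was labelled with Cy5 and hybridized against DNA of input chromatin labelled with Cy3. Per the labels, each deposited column is the mean of 3 replicates after normalization to a gene list. The members of that list, the background correction, the spot filters and the array design are not given in the sources used here. Replicate arrays and spot intensities were not used here, and the number of columns of values that could not be mapped to a sample was 0.

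The unit was taken as a score, a number without a fixed range, because the deposited values lay near 0 with both signs and the labels name neither a log base nor a direction of the ratio. The deposited medians were -0.00875 in untreated cells, 0.0527 at 30 min and 0.0168 at 120 min, and the robust SDs (1.4826 times the median absolute deviation) were 0.388, 0.442 and 0.512. The design written before the data were examined assumed a log2 ratio of immunodepleted over input DNA, in which loss with Maf1 gives low values. Pol III-named features lay high, so under that direction they would show no loss with Maf1. That goes against the assumed direction if Maf1 sat at these genes, which the values alone cannot settle. The scale and the direction therefore stay unknown, both tails are given, no folds are given, and differences are in score units.

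Each column was centred on its median over all measured features, and changes between conditions were taken as differences of centred scores per feature. There is 1 column per condition and hence no test between samples. For each list of features the median was set as a percentile among the medians of 10000 random lists of the same size, drawn from all features with a value. The lists were not matched on level, because no intensities were used. Random lists also drew on Pol III-named, Ty and LTR features and on neighbours of Pol III genes. Lists of protein genes were thus not set against protein genes alone. The percentile describes these columns only. Each list was compared for every level and change without correction for their number, so some medians would fall outside a central 95% range by chance. Features above or below 3 robust SDs of their own column were counted, with the opposite tail as the background. Overlaps were set against the number expected for independent lists, and correlations were computed across features. Intervals used to judge alternatives are 95% bootstrap intervals over list members from 2000 draws, and cover the spread between features, not between arrays.

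Lists were fixed before the data were examined. They are tRNA genes, other Pol III genes, ribosomal DNA transcribed by RNA polymerase I, ribosomal protein genes, ribosome biogenesis genes, genes under nitrogen catabolite repression, stress genes of Msn2 and Msn4, glycolytic genes, histone genes, genes of Gcn4 and amino acid synthesis, small RNA genes of RNA polymerase II, genes of the Pol III machinery, Ty and LTR elements, centromeres and mitochondrial features. Lists of replication origins and of telomere elements matched 0 features and were not used here. A feature joined a list through the name in its identifier. Of 6399 features 250 were named for tRNA genes, 7 for other Pol III genes, 249 for Ty or LTR elements and 5806 for ORFs. Gene symbols and the order of neighbouring genes came from a RefSeq gene table of assembly R64, which matched 5525 of the ORF-named features and left 281 unmatched. The genome build of the array design is not given in the sources used here, so no coordinates are printed. The table names nuclear tRNA genes by another system, so tRNA names are those in the identifiers.

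Features named in the text follow a rule fixed before the data were examined: the 10 lowest scores of each column among features measured in all 3 columns, the 10 lowest and the 10 highest changes from untreated cells to 30 min and to 120 min, every feature named for a Pol III gene other than a tRNA gene, in each described list the 2 lowest and 2 highest changes at each time, and MAF1. The 10 highest scores of each column, the features next to Pol III genes and the high features without a Pol III or Ty name or a known Pol III neighbour were added after the values had been seen, and so was the class of ORF-named features next to a Pol III gene. Higher and lower stand for the sign of a difference of centred scores and for no test.

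The percentile procedure was tested on simulated data from the 6277 features measured in all columns. Each column was shuffled on its own, 200 features were shifted in the 120 min column, and differences from untreated cells were then taken. Fewer random lists were drawn than for the data. Shuffling columns separately removed the correlation between them, so the simulated differences do not have the spread of the real ones. The percentiles that follow hold for the simulated columns only. A shift of 0 gave a list median at percentile 63.2, a shift of 0.1 one at percentile 97.8 and a shift of 0.7 one at percentile 100. Alternatives were the deposited values without centring, centring on features without a Pol III name, columns scaled to equal spread, quantile normalization, means in place of medians, features measured in all columns, and limits of 2 and 4 robust SDs or 1 fixed limit. Centring by chromosome and leaving out neighbours of Pol III genes were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.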

Results

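Maf1, the conserved repressor of RNA polymerase III (Pol III), was followed on chromatin of budding yeast before and during treatment with rapamycin, an inhibitor of the TOR kinase that controls growth in response to nutrients. Pol III transcribes the tRNA genes, the 5S ribosomal RNA genes and a few other small RNA genes. Crosslinked chromatin that carried myc-tagged Maf1 was depleted of Maf1 with antibodies, and the DNA left after depletion was set against the input DNA on intergenic DNA microarrays, as the series design describes. There were 3 conditions, each with 1 deposited column that is the authors' mean of 3 replicate arrays: untreated cells, cells after 30 min and cells after 120 min in rapamycin at 0.2 ng/ul. The table held 6399 array features, of which 6284, 6282 and 6279 had a value in the 3 conditions and 6277 had a value in all of them. No spread between replicates could be had from averaged columns, so none of the differences below has a replicate check and no p-value is given. The number of arrays limits the precision.

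Values are the deposited scores minus the median score of the column, in score units. The labels do not state the log base or which DNA fraction is on top of the ratio, so a higher score is not read here as more or less Maf1. With the sign turned, every higher score below reads as a lower one. A feature that carries the name of a tRNA gene, of another small RNA gene or of a retrotransposon element was assigned to that element, and a feature that carries the name of an open reading frame (ORF) was assigned to that ORF. Such a name does not place the feature: the labels do not say which side of the ORF it covers, so a value at an ORF is that of a stretch beside it, which may lie downstream and nearer to another gene. Scores beside Pol III genes, given under other observations, argue against the lower-coordinate side for most such features there.

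The first question was where along the genome the score stood apart in each condition. Features named for tRNA genes had high scores in all 3 conditions. The median over the 245 measured tRNA-named features was 0.76 in untreated cells, 0.62 after 30 min and 1.46 after 120 min in rapamycin. Each of these medians lay above that of every one of 10000 random lists of the same size, whose highest medians were 0.11, 0.13 and 0.15. Of the 245 features, 235 lay above the column median in untreated cells, 231 after 30 min and 238 after 120 min. In untreated cells the tRNA-named features with the highest scores were tD(GUC)G1 at 1.62, tT(AGU)I1 at 1.61, tD(GUC)J2 at 1.58 and tL(CAA)G2 at 1.52, for tRNAs of aspartate, threonine and leucine. After 120 min they were tS(AGA)G at 2.50, tH(GUG)K at 2.41, tQ(UUG)D2 at 2.38, and tI(AAU)N1 and tC(GCA)B, both at 2.35. Features with the highest scores in a column were listed after the values had been seen, because the rule fixed beforehand took the lowest ones.

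The other Pol III genes did not all follow the course of the tRNA-named median. RPR1, the RNA of RNase P, stood at 0.85 in untreated cells, at 0.74 after 30 min and at 2.23 after 120 min. SCR1, the RNA of the signal recognition particle, followed the same course with 0.76, 0.56 and 2.22. SNR6, which encodes the U6 spliceosomal RNA, started near the column median at 0.09 and stood at 0.79 and 1.92 in rapamycin. SNR52, a small nucleolar RNA gene, stood at 0.16, 0.62 and 0.29. The 5S ribosomal RNA features RDN5-1, RDN5-2 and RDN5-3 had 0.09, 0.34 and 0.09 in untreated cells and 0.52, 0.60 and 0.30 after 120 min. The median over these 7 features was 0.16 in untreated cells, at percentile 83.9 of random lists, 0.56 after 30 min, at percentile 99.9, and 0.60 after 120 min, at percentile 98.8. The 5S genes are repeated on the chromosome and near-identical, so their features may not be told apart by hybridization.

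**Figure D1:**
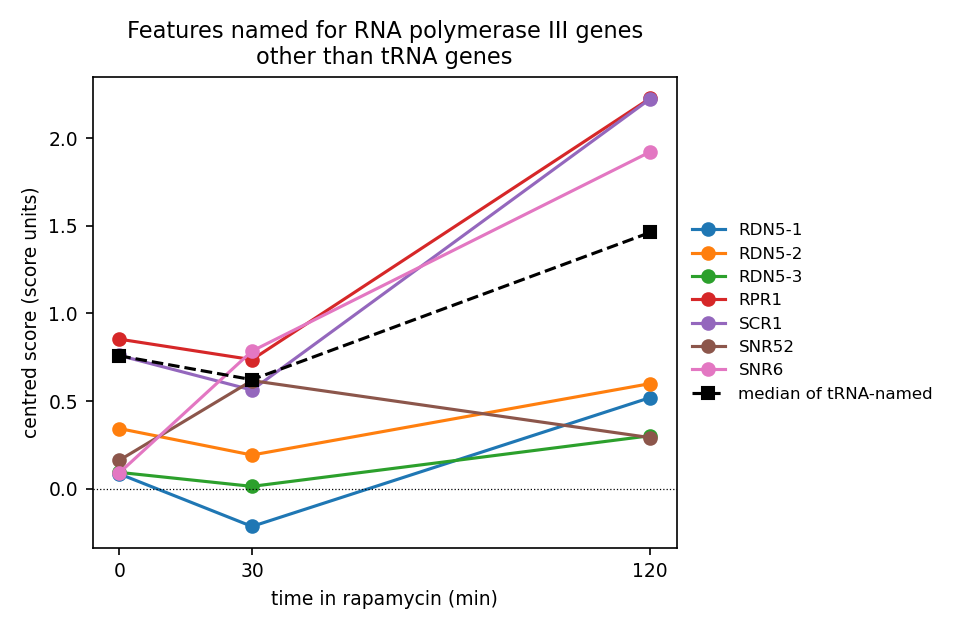
Centred score (score units, vertical axis) of each feature named for a Pol III gene other than a tRNA gene against time in rapamycin (min, horizontal axis), with the median of the 245 tRNA-named features as black squares. Each point is 1 averaged column without an error bar; RPR1, SCR1 and SNR6 ended at 2.23, 2.22 and 1.92, above the tRNA median of 1.46, and SNR52 at 0.29.

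Features named for Ty retrotransposons and their long terminal repeats (LTRs), which lie near many tRNA genes, also had raised scores. Nearly all were LTRs, with 200 delta, 21 tau, 13 sigma and 10 omega features measured, and only 1 was named for a Ty element itself. The median over 245 measured Ty and LTR features was 0.29 in untreated cells, 0.30 after 30 min and 0.38 after 120 min, each above that of every random list. Their scores were uneven, with an upper quartile of 1.31 and a lower quartile of -0.02 after 120 min. The neighbours of Ty and LTR features were not looked up. Those beside a tRNA gene could hence not be told from the others, and the raised median may not belong to the repeats themselves. The feature of the ribosomal RNA gene RDN37-1, transcribed by RNA polymerase I, had a score of 0.84 in untreated cells and no value in the rapamycin columns. The feature of MAF1 itself stood at -0.37, 0.33 and 0.03.

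**Figure D2:**
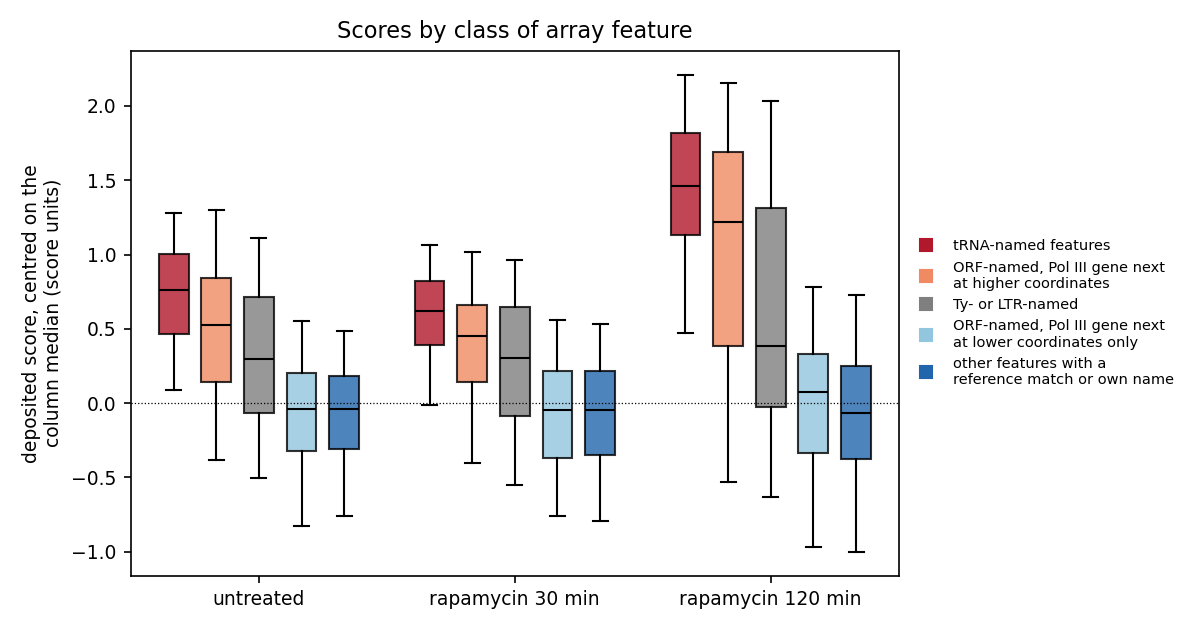
Centred score (score units, vertical axis) by condition for 5 classes of array features; boxes span the quartiles with the median as a line, and whiskers reach from the 5th to the 95th percentile of the features. The tRNA-named class had medians of 0.76, 0.62 and 1.46, and the class of ORF-named features with a Pol III gene next at lower coordinates stayed near 0.

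The second question was what 120 min of rapamycin did to these scores. The tRNA-named features scored higher after 120 min than in untreated cells by a median of 0.72. Of these, 234 of 245 changed in that direction, where 43.9% of all features changed in the other. The median lay above that of every random list, whose central 95% range was 0.00 to 0.13. Features of tRNAs for each of the 20 amino acids shared the direction, with medians between 0.53 for proline (12 features) and 1.08 for cysteine (3 features), and so did tRNA-named features on each of the 16 nuclear chromosomes. The largest differences were 1.63 at tI(AAU)N1 and 1.55 at tH(GUG)K. The lowest were -1.06 at 1 feature of tS(UGA)E and -0.61 at 1 feature of tW(CCA)K, both from stretches covered by several numbered features. Among the other Pol III genes all 7 were higher after 120 min, by 1.83 at SNR6, 1.46 at SCR1, 1.37 at RPR1, 0.43 at RDN5-1, 0.26 at RDN5-2, 0.21 at RDN5-3 and 0.13 at SNR52. Their median of 0.43 was at percentile 96.6 and inside the central range of random lists of 7, which was -0.34 to 0.46.

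Ty and LTR features were higher after 120 min by a median of 0.29, with 170 of 245 above 0. Of all features 43.9% lay below 0 for this change, so an even split is not the background of such counts. The largest difference among them was 2.53 at YDRWdelta25, which reached 3.43, the highest score of that column, and the next was 2.19 at YNLWdelta4. The 138 features of ribosomal protein genes changed by a median of -0.06, at percentile 0.25 of random lists, with 77 below 0 and 61 above. The bootstrap interval of that median, -0.17 to 0.03, held 0, but the random range was -0.02 to 0.15 and not centred on 0. The median was -0.03 with the spread made equal and -0.11 with each chromosome centred separately, each below its random range. Their level after 120 min was -0.12, at percentile 1.21 and below a random range of -0.11 to 0.10, with a bootstrap interval of -0.22 to -0.06 and 89 of 138 below 0. The random lists held the raised Pol III and Ty features. ORF-named features with no Pol III gene next had medians of -0.07 for this level and 0.02 for the change. Both bootstrap intervals held these values, so ribosomal protein genes were not shown to stand apart from other ORFs. RPL15A and RPS0B changed by -1.80 and -1.66, and RPL20A and RPS4A by 1.12 and 1.09. The column at 120 min also had a wider spread, with a robust SD of 0.512 against 0.388 in untreated cells. With the spread of the columns made equal, the tRNA median change was 0.42 and the Ty and LTR one 0.15. After quantile normalization the tRNA change was 0.12, still above the random range, and the Ty and LTR change was 0.02, inside it.

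The single features that changed most between untreated cells and 120 min were mostly named for ORFs with no Pol III gene beside them. So were most features of the array, 4986 of the 6278 with a value for this change. Among ORF-named features the highest changes were 2.74 at OM14, which encodes a mitochondrial outer membrane protein, and 2.42 at IPT1, an enzyme of sphingolipid synthesis. Both started from scores below -2, at -2.06 and -2.23, so that they ended at 0.68 and 0.19. SIP18, LDO45, HXT11, ATO3 and YBL055C changed by 2.38, 2.21, 2.15, 2.15 and 2.03. They started low in untreated cells too, from -1.82 at HXT11 to -0.96 at YBL055C. VAC8, a vacuolar membrane protein gene, changed by 2.27, reached 2.07 and has a tRNA gene next to it at higher coordinates. The lowest changes were -3.36 at OSH6, an oxysterol-binding protein homologue, -3.01 at DCN1, -2.82 at PRE8, which encodes a proteasome subunit, and -2.69 at the vacuolar aminopeptidase gene APE1. They were followed by -2.64 at REX3, -2.56 at AIM6, -2.44 at ABZ2, -2.43 at IML2, -2.42 at MDM38 and -2.37 at the telomere protein gene RIF2. REX3 lies next to SNR6 and stood at -3.03 after 120 min, while SNR6 stood at 1.92.

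The next comparison asked whether the change was already present after 30 min. It was not, and the tRNA-named features scored slightly lower after 30 min than in untreated cells. Their median change was -0.14, with 163 of 245 below 0, and it lay below that of every random list. The lowest values were -1.12 at tD(GUC)J2 and -0.96 at 1 feature of tS(UGA)E, and the highest were 1.80 at tV(AAC)E1 and 0.94 at tQ(UUG)B. The other Pol III genes had no common direction at 30 min, with 0.69 at SNR6, 0.45 at SNR52, -0.20 at SCR1, -0.30 at RDN5-1, -0.15 at RDN5-2, -0.12 at RPR1 and -0.08 at RDN5-3. Their median of -0.12 was at percentile 23.2. Ty and LTR features changed by a median of -0.05, inside the random range, and by -0.09 with the spread made equal, outside its range of -0.06 to 0.05. The tRNA median change at 30 min was -0.22 with the spread made equal, -0.07 after quantile normalization and -0.08 without centring.

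The 19 measured features of glycolytic genes changed by a median of 0.18 at 30 min, at percentile 98.3, and 16 of them were above 0. With many lists and changes examined, some medians would lie this far out by chance. Without the 1 feature beside a Pol III gene the median was 0.16 over 18 features, at percentile 96.9 and inside the central random range. HXT1, a glucose transporter gene placed in this list, and CDC19, the pyruvate kinase gene, changed by 1.02 and 0.83, and FBA1 and ENO2 by -0.74 and -0.30. Single features with the highest changes at 30 min were 3.85 at IPT1, 3.67 at OM14 and 2.86 at DIP5, a dicarboxylic amino acid permease gene. RPS16A, RIT1, LRG1, SND1, YPL071C, HXT11 and COT1 changed by 2.35, 2.32, 2.25, 2.15, 2.13, 2.08 and 2.01. All of these started low in untreated cells, from -2.76 at DIP5 to -0.92 at RIT1. DIP5, YPL071C and HXT11 ended near the column median, at 0.10, -0.10 and 0.26. Such changes may thus reflect low untreated scores in 1 averaged column, which was not tested. The lowest changes were -2.75 at SCS2, an endoplasmic reticulum membrane protein gene, -2.39 at BRE1, a histone ubiquitin ligase gene, and -2.29 at YCL065W. THI5, GET1, MRP20 and NCB2 changed by -2.09, -2.08, -2.03 and -2.00. They were followed by -1.96 at the protein kinase gene NPR1 and by -1.86 at both SCO1 and SPR6.

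Between 30 and 120 min the tRNA-named features scored higher by a median of 0.87, with 236 of 245 above 0 and a median above that of every random list. Of all features 43.1% lay below 0 for this change. The other Pol III genes were higher by a median of 0.73, at percentile 99.8, and 6 of 7 were above 0. After quantile normalization that median was 0.28, inside the random range. The exception was SNR52, at 0.62 and then 0.29. Ty and LTR features were higher by a median of 0.26. Glycolytic genes changed by -0.15, at percentile 2.80 and inside the central random range. With equal spread and with each chromosome centred separately they changed by -0.17 and -0.20, outside the ranges, whose lower ends were -0.15 and -0.17. Their level after 120 min was -0.29, at percentile 1.99 and below a range of -0.28 to 0.29, but -0.23 and inside the range with each chromosome centred separately. The random lists held the raised Pol III and Ty features. ORF-named features with no Pol III gene next had a median level of -0.07, which the glycolytic bootstrap interval of -0.44 to -0.03 held. The tRNA median change from 30 to 120 min was 0.68 with equal spread and 0.22 after quantile normalization.

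**Figure D3:**
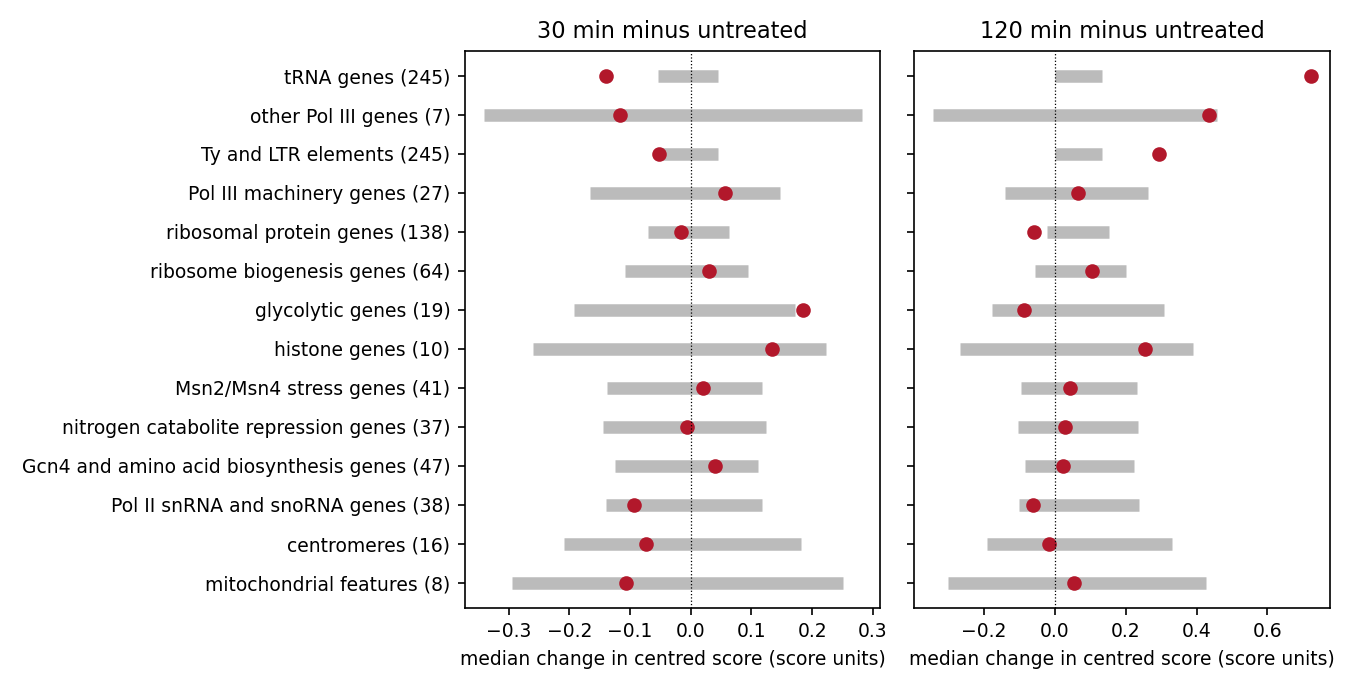
Median change in centred score (score units, horizontal axis) of each list of features, with the number measured in brackets, from untreated to 30 min (left) and to 120 min (right). Red points are list medians and grey bars the central 95% range of 10000 random lists of the same size; tRNA genes lie at -0.14 on the left and at 0.72 on the right.

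The remaining lists, those of the Pol III machinery included, stayed inside the central range of random lists at 30 and at 120 min. Under equal spread, quantile normalization, no centring and centring by chromosome there was 1 exception, the small RNA genes of RNA polymerase II at 120 min with equal spread, at -0.11 and below a range of -0.09 to 0.22. From untreated cells to 120 min the median change was 0.11 over 64 ribosome biogenesis genes, 0.03 over 37 genes under nitrogen catabolite repression and 0.04 over 41 stress genes of the Msn2 and Msn4 regulators. It was 0.02 over 47 genes of Gcn4 and amino acid synthesis, 0.25 over 10 histone genes and -0.06 over 38 small nuclear and nucleolar RNA genes of RNA polymerase II. The 27 genes for Pol III subunits and transcription factors changed by 0.07, the 16 centromeres by -0.02 and 8 mitochondrial features by 0.05. At 30 min the same lists, in the same order, changed by 0.03, -0.01, 0.02, 0.04, 0.13, -0.09, 0.06, -0.07 and -0.11. Members of these lists moved in both directions. In the nitrogen list DIP5 changed by 1.65 at 120 min and DAL3 by -1.09. In the stress list GSY1, a glycogen synthase gene, changed by 1.65 and PRX1 by -0.99. Among ribosome biogenesis genes ERB1 and RPA135, both with a tRNA gene next at higher coordinates, changed by 1.30 and 1.13, and DIP2 and RLP24 by -2.25 and -1.89. In the amino acid list CPA1 and ARG8, both of arginine synthesis, changed by -2.27 and -1.33, and MET6 by 0.73.

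The number of features far from the column median was counted with a limit of 3 robust SDs of the column. In untreated cells 80 features lay above and 75 below it. After 30 min there were 7 above and 44 below, and after 120 min 266 above and 105 below. Features named for Pol III genes made up 34 of the 80 high features in untreated cells (42.5%), 1 of 7 after 30 min (14.3%) and 119 of 266 after 120 min (44.7%). They made up 0 of the low features in each condition, against 252 of 6284 measured features in untreated cells. With each chromosome centred separately, an alternative chosen after seeing the data, the 30 min counts were 24 above and 40 below. The untreated count above the limit was higher in this way and lower with 1 fixed limit for all columns, as given below.

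In untreated cells and after 120 min, most high features without a Pol III name were named for ORFs whose next gene at higher coordinates is a Pol III gene, 22 and 85 features, or for Ty or LTR elements, 12 and 50 features. After 30 min there were 1 and 2 of these kinds and 3 others. Pol III-named features and these ORF neighbours together made up 76.7% of the high features after 120 min, 70% in untreated cells and 28.6% after 30 min, a grouping made after seeing the data. Among the neighbours were PUT1, the proline oxidase gene, at 1.60, 1.03 and 2.17 in the 3 conditions, COQ8 at 1.51, 1.15 and 2.28, and NUP192 at 1.41, 0.91 and 2.38. RAD14, next to the Pol III gene RNA170, stood at 0.40, 1.04 and 1.63. YLR159W and YLR161W, each next to a 5S gene, stood at 0.70, 0.27 and 1.76 and at 0.73, 0.42 and 1.66. PMD1, next to SNR52, stood at 0.05, 0.44 and 0.38.

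The low features were mostly outside the Pol III and Ty classes and beside no known Pol III gene, as were 94 of the 105 after 120 min. Most features of the array were of that kind, 5070 of 6279 measured at 120 min. The lowest scores in untreated cells were -2.76 at DIP5, -2.68 at the protein kinase gene KIN2, -2.23 at YPL071C and at IPT1, and -2.21 at the translation initiation factor gene PRT1, followed by OM14, YGL046W, UTP8, AKR2 and SLT2 at -2.06, -2.04, -1.96, -1.92 and -1.91. After 30 min they were -4.11 at KIN2, -2.90 at SRN2, -2.41 at THI5, -2.39 at MRP20 and -2.30 at RPL12A, followed by NCB2, SCO1, YEL073C, YCL065W and SPR6 at -2.28, -2.25, -2.24, -2.21 and -2.19. After 120 min they were -3.42 at DCN1, -3.28 at OSH6, -3.03 at REX3, -2.90 at KIN2 and -2.86 at PRE8, followed by CPA1, ABZ2, MSL5, ISY1 and KNS1 at -2.55, -2.53, -2.32, -2.29 and -2.28.

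High features recurred between untreated cells and 120 min, with 63 shared where independent lists of these sizes would share 3.39. Untreated cells and 30 min shared 0 high features and 30 and 120 min shared 1, where 0.0892 and 0.297 would be shared by independent lists, so 7 high features at 30 min were too few to compare. With a limit of 2 robust SDs these pairs shared 79 and 85. Of the low features, untreated cells shared 8 with 30 min and 4 with 120 min, where 0.526 and 1.25 would be shared by independent lists, and 30 and 120 min shared 2 against 0.736. The features of KIN2 and SRN2 were low in all 3 conditions. Across the 6277 features measured throughout, Pearson's r was 0.552 between untreated cells and 30 min, 0.592 between untreated cells and 120 min and 0.584 between 30 and 120 min, so the columns run in the same direction. Spearman's rho was 0.565, 0.567 and 0.607. Over the 252 Pol III-named features r was 0.586, 0.706 and 0.680 in the same order. These correlations are across features, which are not independent replicates.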

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

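Centring by chromosome and the restriction to ORF-named features with no Pol III gene next were chosen after seeing the data. No list median that lay outside the central random range changed its sign under any alternative run. Changes of sign were not counted for medians inside that range. The first group of values held those of tRNA-named features, the counts, the Pol III shares, the overlaps and the correlations. Of these 99 stayed within their interval or within 1.5 times the count and 49 moved. Of the values of all other lists 681 stayed and 21 moved. This count overstates stability. Leaving out neighbours removed no member of the Ty and LTR, centromere, histone, mitochondrial and RNA polymerase II small RNA lists, so those values stayed by construction. Bootstrap intervals of short lists are also wide. For tRNA-named features equal spread gave 0.87 untreated, 1.28 at 120 min, and changes of -0.22 at 30 min, 0.42 at 120 min and 0.68 from 30 to 120 min. Quantile normalization gave 0.94, 0.80 and 0.98 in the 3 conditions and changes of 0.12 from untreated to 120 min and 0.22 from 30 to 120 min; the cause was not tested. Without centring the 30 min level was 0.67. Counts follow the limit by construction. At 2 robust SDs there were 312 features above and 273 below in untreated cells, 115 and 196 at 30 min, and 477 and 273 at 120 min, with 1 Pol III-named feature among the low ones at 30 min and 1 at 120 min. The share named for or next to a Pol III gene among high features was then 59.0% untreated and 69.0% at 120 min. At 4 robust SDs there were 8 above and 20 below in untreated cells, 0 and 17 at 30 min, and 66 and 28 at 120 min, and that share was 81.8% at 120 min. With 1 fixed limit there were 33 above and 41 below in untreated cells. With each chromosome centred separately 124 lay above in untreated cells and 24 at 30 min; the cause was not tested. Shared features at 2 robust SDs were 79 high and 46 low for untreated and 30 min, 237 and 47 for untreated and 120 min, and 85 and 36 for 30 and 120 min. At 4 robust SDs they were 1 low for untreated and 30 min, 1 high and 1 low for untreated and 120 min, and 0 high and 1 low for 30 and 120 min. Without Pol III-named features r was 0.508, 0.527 and 0.535 for these pairs, and over ORF-named features with no Pol III gene next it was 0.444, 0.410 and 0.471. Leaving out shared Ty features, counting repeated spots singly and leaving out replicates gave no value, since 0 features were named for both a Pol III gene and a Ty or LTR element, 0 identifiers were repeated, and each condition has 1 averaged column. No paired analysis was possible because each condition has 1 column. The number of arrays limits precision, and signal over background was not analysed here.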

Other observations

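Every test in this part was chosen after the result was seen. ORF-named features carried raised scores where the next gene at higher coordinates was a Pol III gene. The 217 such features without a Pol III gene on their other side had medians of 0.53, 0.45 and 1.22 in untreated cells, at 30 min and at 120 min, above every random list of their size. A further 15 measured features with Pol III genes on both sides, among them YNL035C at 2.74 at 120 min, were left out of these medians but counted among the 232 neighbours from which the high features were taken. The 202 features with a Pol III gene next at lower coordinates only had -0.04, -0.04 and 0.07, inside the central random range. Features with no Pol III gene next had -0.04, -0.05 and -0.07. Where the tRNA gene was the second gene at higher coordinates and not the first, the median at 120 min was -0.06 over 193 features. In stretches covered by several numbered features with a tRNA gene next at higher coordinates, the highest-numbered feature had a median of 1.21 at 120 min (10 features) and the lower-numbered ones 0.12 (11 features). These values argue against ORF-named features lying mostly on the lower-coordinate side, for the ORFs they cover. For an ORF read toward higher coordinates, the other side is downstream of it.

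Repeat families had overlapping scores, and differences between them were not tested. At 120 min the 200 delta elements, LTRs of Ty1 and Ty2, had a median of 0.42 with quartiles of -0.08 and 1.35, and the 21 tau elements of Ty4 had 0.49 with quartiles of 0.11 and 1.71. The 13 sigma elements of Ty3 had 0.31 with quartiles of 0.16 and 0.50, and the 10 omega elements of Ty5 had 0.19 with quartiles of -0.15 and 0.31. The change from untreated cells was 0.40 at sigma, 0.35 at tau, 0.28 at delta and 0.03 at omega elements. Features above 3 robust SDs at 120 min that are named for ORFs of the reference table with no Pol III gene next were YDC1 at 2.32, DIA3 at 1.95, KTR1 at 1.75, MGA1 at 1.67 and NNF2 at 1.66. The small nucleolar RNA gene SNR53, whose neighbours were not looked up, stood at 1.54. In untreated cells YDC1 and KTR1 stood at 0.60 and 0.33 and DIA3 at 1.04.

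For the higher tRNA scores at 120 min, the median change with the spread of the columns made equal was 0.42. Its bootstrap interval of 0.36 to 0.51 lay above the random range of 0.01 to 0.13. This argues against the larger robust SD of the 120 min column as the whole cause, though part of the 0.72 went with it. After quantile normalization, which makes the whole distributions equal, the tRNA median change was 0.12, so most of the 0.72 went. The tRNA-named features make up much of the high tail, so that step cannot tell a real rise from a wider column. With each chromosome centred separately the change was 0.71, which argues against offsets between whole chromosomes, while gradients within a chromosome were not tested. Whether the immunodepletion differed in its completeness between conditions was not tested and stays open, since each condition is 1 averaged column and the direction of the ratio is unknown. An effect of the time in rapamycin stays open too, as untested.

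Among ORF-named features beside a tRNA gene at higher coordinates and none at lower ones, those whose tRNA gene points away from the feature (102 features) had a median of 0.64 at 120 min, and those whose tRNA gene points toward it (111 features) had 1.45. The lower quartile differed by 1.14 and the upper quartile by 0.09, a gap of 1.04 between the differences (0.69 to 1.31), which argues against a uniformly lower score upstream of tRNA genes. The lower quartile of the first set was -0.14 (-0.37 to 0.18), a range that holds the median of -0.07 for features with no Pol III gene next. A part of the first set may thus not reach the tRNA gene, for instance where an LTR with a feature of its own lies between. The lower quartile alone does not give the size of that part. No biological explanation was tested, since the design names none for this contrast.

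Very low scores lay on different chromosomes at 30 and at 120 min, by a division of the chromosomes drawn from these counts. Among ORF-named features with no Pol III gene next, 1 of 1527 on chromosomes I to VI and 93 of 3460 on VII to XVI were below -3 robust SDs at 120 min, against 30 of 1527 and 9 of 3462 at 30 min; in untreated cells they were 26 of 1530 and 43 of 3461, without such a split. Chance placement of features is unlikely, since shuffling features between chromosomes gave counts as uneven over the 16 chromosomes at 120 min, without any division into groups, in a share of 0.0001, the smallest that 10000 shuffles can give. With each chromosome centred separately 2.75% on VII to XVI (2.23 to 3.35) were still very low, an interval above that for I to VI. That the share remained argues against a lower median of whole chromosomes. Between the 2 groups the 1st and 99th percentiles changed by -0.82 and 0.00, a sum of -0.81 (-0.95 to -0.60). The division was drawn from the low scores, so a fall of the 1st percentile was built in, and no interval here allows for that. The sum therefore cannot decide whether noise widened both tails. The 99th percentile, which was not used to draw the division, did not rise. The order in which features were printed or amplified was not analysed here and stays open, and no biological explanation was tested.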
